A study of Mus musculus with 16 samples.

How the data were processed

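RNA from 16 mouse livers was hybridised to Affymetrix arrays, 1 array per liver. Per the labels' protocols, 100 ng of total RNA was amplified and biotin-labelled with a whole-transcript kit for each array. The labels place 8 livers in each of the 2 genotypes, LRH-1 hep+/+ (called control here) and LRH-1 hep−/− (called knockout here), and describe the livers as biological replicates numbered within each genotype. No sex, batch or scan date is given in the sources used here.

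The deposited values are linear probe-set intensities made by the authors with Affymetrix Expression Console, per the submitters' processing notes, which name no version. The summary algorithm, the background correction and the between-array normalization are not given in the sources used here. The values were all above 0 and the array medians lay between 38.9 and 43.5, which set the scale as linear, and the log2 distributions of the arrays were close but not identical. Scanner files were not used here. The values of the 16 arrays were taken to log2 with no pseudocount and no further normalization. An authors' normalization that makes arrays alike can hide a shift shared by most genes, so all changes are relative to the other genes of the same array. The number of arrays limits the precision, and no depth applies to array intensities.

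The table held 35556 probe sets. The platform annotation listed 23832 of them, of which 21456 were paired with exactly 1 gene and 2376 with several, and 11724 were not listed and stayed unnamed. For 21277 of the single-gene probe sets the gene identifier was found in a RefSeq table of assembly GRCm38.p6, used for names only, and 2 symbols were updated. Probe sets with several genes or no listing entered no gene-level test. For 1343 genes with more than 1 probe set, the one with the highest mean over all arrays was kept. This left 19237 genes, with no filter on dim probe sets. No 2 arrays held the same values: within a genotype the median absolute log2 difference between arrays was 0.106 or more.

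The genotypes were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) with genotype as the single term, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 19237 genes. A gene was called changed at an adjusted p under 0.05. Values are given as mean ± SD over the 8 livers of a genotype, and changes as knockout minus control on the log2 scale ± SE from the limma fit. Nr5a2 was also tested with an exact permutation test over all 12870 assignments of the arrays. Gene lists for liver pathways, zonation, sex-biased expression and the cell types a liver piece could hold were fixed before the data were examined. They named 714 members, of which 623 were measured by a single-gene probe set, and members with none were not analysed here. The 34 lists with at least 5 measured genes, sex-linked transcripts aside, were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with all other genes. Each list was tested again with a correlation estimated from its own genes and with fry, whose p-value tests whether the genes of a list move, on balance, in the same direction, without comparing them with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

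The genes named in the text follow a rule fixed together with the lists. It takes Nr5a2, then the 10 largest increases and the 10 largest decreases among changed genes, leaving out predicted loci, clones and small RNAs (1 was passed over, among the increases), then for each list up to 4 changed members with the smallest p, or 1 or 2 members given as values where none changed. The rule picked 118 distinct genes. A gene given with values outside it was chosen after its values were seen, apart from the sex-linked transcripts, which were fixed as a check.

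The same steps were tested on simulated data with the means and residual SDs of the 19237 genes and 200 genes changed by known amounts. Of the changed genes, 82% of those shifted by 0.5 log2 unit and 100% of those shifted by 1 log2 unit were recovered, and 5.7% of the 193 calls were false. In a second simulation the bile acid synthesis list, shifted by -0.4 log2 unit, was called lower and 0 of the 33 other lists were called. Simulated genes were independent, so that test does not cover correlation between the genes of a list.

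The alternatives tried were the replicate number as a block, quantile normalization, centring of each array on its median, filters at the 25th and 50th percentiles of mean intensity, the mean of a gene's probe sets, an intensity trend with robust variances, array weights, a minimum change of 1.5-fold, all probe sets in place of genes, the other list tests, and leaving out each array in turn. They were listed at the same stage as the gene lists. After the data were seen, fits without the arrays that held transcripts of muscle or adipose tissue, without the arrays apart on the second principal component, and without these and knockout 3 were added. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.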

Results

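Hepatic transcripts were measured in mice of 17 to 19 weeks that had free access to food and were killed at 7 am. The study compared 8 control livers (LRH-1 hep+/+) with 8 knockout livers (LRH-1 hep−/−), each on its own whole-transcript Affymetrix array. LRH-1, or liver receptor homologue 1, is a nuclear receptor encoded by Nr5a2, and the notation marks a deletion directed to hepatocytes. The comparison asks which liver transcripts depend on LRH-1. The values are the log2 of the deposited intensities, for 19237 genes.

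Nr5a2 itself was lower in every knockout liver than in every control liver. Its log2 intensity was 8.66 ± 0.13 (SD, n = 8) in controls and 7.78 ± 0.37 (SD, n = 8) in knockouts, a change of -0.88 ± 0.12 (SE), or 54.2% of the control level, with an exact permutation p of 0.000155, the smallest that 12870 assignments allow. Controls spanned 8.45 to 8.78 and knockouts 7.25 to 8.25. The probe set can also read exons outside the deleted part, which the labels do not specify, and transcripts of cells in which the gene was left intact.

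In knockout livers the transcripts of the sterol 12-alpha-hydroxylase Cyp8b1, of the nuclear receptor gene Nr0b2 and of some bile acid and lipoprotein genes were lower. Those of Cyp2b9, Tff3, Cidec and 9 of 17 genes of a proliferation list, which holds the cell cycle inhibitor gene Cdkn1a, were higher. In limma, 1673 genes changed at a Benjamini-Hochberg adjusted p under 0.05, 1057 higher and 616 lower in knockout. Of these, 257 rose and 164 fell by at least 1.5-fold, and 101 rose and 55 fell by at least 2-fold. For 556 of all 19237 genes the 2 genotypes did not overlap in any liver, where chance gives 0.0155% of genes. Of these, 553 were among the called genes. Centring each array on its median reduced the higher share of the calls from 63.2% to 53.4%, so the excess of increases was small on that scale.

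The largest decrease was in Cyp8b1, which encodes the sterol 12-alpha-hydroxylase that sets the cholic acid share of bile acids. It went from 10.51 ± 0.29 to 6.28 ± 0.43, a change of -4.23 ± 0.16 (SE, limma adjusted p = 4.85e-13). Nr0b2, which encodes SHP, a repressor of bile acid synthesis, fell by 4.02 on the log2 scale (SE 0.20, limma adjusted p = 1.9e-11). Other large decreases were in Apon (-3.39), Mrap (-2.65), an accessory protein of the melanocortin receptors, Camk1d (-2.62), a calcium-regulated kinase, Susd4 (-2.29), Paqr9 (-2.25), Rhbg (-1.99), an ammonium transporter, Slc22a7 (-1.94), an organic anion transporter, and Hgfac (-1.89), the activator of hepatocyte growth factor. All of these had limma adjusted p-values of 1.34e-06 or lower, and none overlapped between genotypes.

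The largest increase was in Cyp2b9, a cytochrome P450 typical of female mouse liver, from 4.46 ± 0.50 to 10.40 ± 0.78, or 61.5-fold (5.94 ± 0.28 SE on the log2 scale, limma adjusted p = 8.94e-12). Tff3, a secreted trefoil peptide, rose by 3.53 ± 0.22. Cyp2d12 (3.37), Cyp2a22 (3.25) and Cyp2c55 (2.78) were further P450 genes among the 10 largest increases. Abcb1b, a multidrug efflux pump, rose by 2.92 ± 0.17. Cidec (2.83 ± 0.26) and Cidea (2.78 ± 0.32) encode proteins of the lipid droplet surface. Smcp rose by 3.07, with knockout 8 at 5.71 and the other knockouts at 7.15 or more, and Cib3 rose by 2.97, with control 2 at 5.72 and the other controls at 5.19 or less. Among these 10 genes only Cidea overlapped between genotypes. There control 5, an array with adipose transcripts, stood at 6.41 and the other controls at 5.16 or less. Knockout 8 stood at 5.97 and the other knockouts at 6.83 or more.

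**Figure D1:**
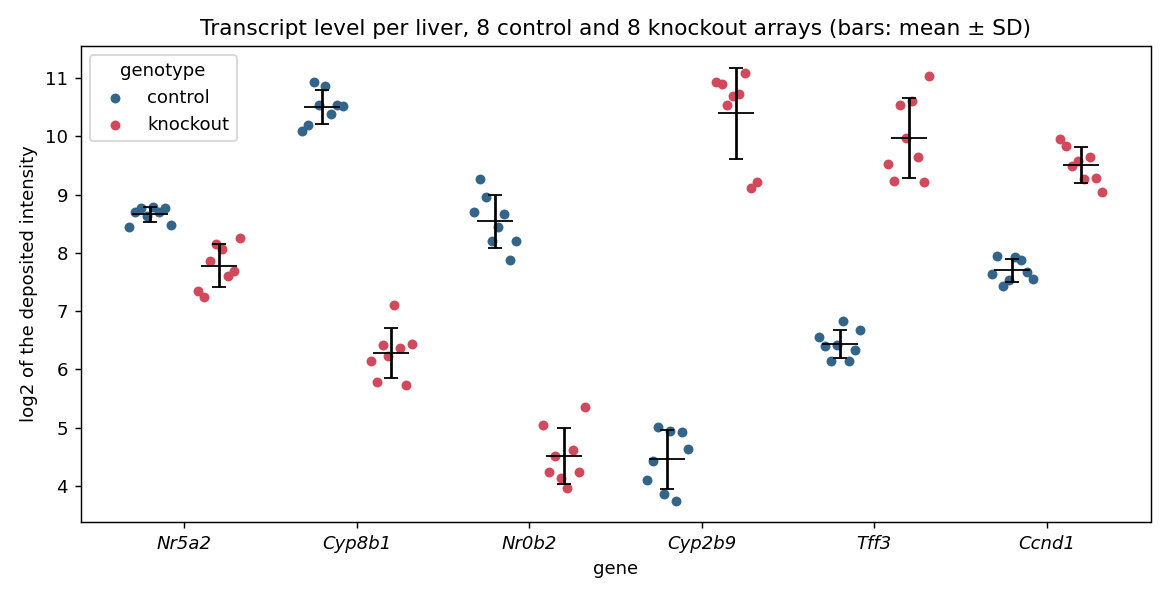
Log2 of the deposited intensity of 6 genes in each of the 8 control (blue) and 8 knockout (red) livers, with 1 point per liver and black bars for the mean ± SD. Nr5a2, Cyp8b1 and Nr0b2 lie lower and Cyp2b9, Tff3 and Ccnd1 higher in all 8 knockout livers, with no overlap between genotypes.

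Genes reported as LRH-1 targets moved down as a group. Of 11 measured members 8 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 1.22e-16, median -0.61). Beside Cyp8b1 and Nr0b2, Apom, the lipoprotein carrier of sphingosine-1-phosphate, fell by 1.82 on the log2 scale (SE 0.10) and Scarb1, the hepatic receptor for high-density lipoprotein, fell by 1.05 on the log2 scale (SE 0.08). Apom stood highest in knockout 8, at 7.12 against 6.52 or less in the other knockouts. Plk3, also among the 8, lost its call with an intensity trend and robust variance (adjusted p = 0.0745). Cyp7a1, the rate-limiting enzyme of bile acid synthesis and a member of the list, did not pass the test. Its change of -0.41 ± 0.33 (limma adjusted p = 0.646) came with an SD of 1.03 among knockouts, and it is named here after its values were seen.

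Most bile acid genes that moved went down. These lists share Cyp7a1, Cyp8b1, Nr0b2 and Abcb11 with the reported targets. In the synthesis list 6 of 17 genes fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 3.76e-06). Akr1d1, the steroid 5-beta-reductase, fell by 0.62 on the log2 scale (SE 0.10), Cyp46a1 changed by -0.32 ± 0.07 and Cyp27a1, the sterol 27-hydroxylase, by -0.25 ± 0.05. In the list of FXR signalling and bile acid transport 10 of 19 genes fell and 2 rose, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.3e-08). Slc10a1, the main bile acid uptake carrier of hepatocytes, changed by -0.79 ± 0.06 and Slco1a1 by -0.67 ± 0.08, while the organic anion transporter Slco1a4 rose by 1.84 ± 0.16. Nr1h4, which encodes FXR, changed by -0.57 ± 0.08 (limma adjusted p = 6.58e-05).

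Lipoprotein and cholesterol genes were lower where they moved, with Lpl, named after its values were seen, as the exception (1.76 ± 0.34). In the lipoprotein and cholesterol transport list 5 of 24 genes fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000406, median -0.03). This list shares Scarb1, Abcg5, Abcg8 and Apom with the reported targets, so its call is not a separate result. Apof changed by -0.51 ± 0.07 and Abcg5, which with Abcg8 exports sterols into bile, by -0.53 ± 0.09. In the cholesterol synthesis list 3 of 20 genes fell and 0 rose, or 5 and 0 adjusted over the list alone. They were Mvd (-0.53 ± 0.12), Msmo1 (-0.48 ± 0.13) and Tm7sf2 (-0.47 ± 0.07). Camera called this list lower (adjusted p = 2.5e-06, median -0.23), a call not kept with adjusted p = 0.267 with an estimated correlation. The mean of the list was lowest in knockout 3, at 8.79 against 9.25 or more in the other knockouts. Msmo1 did not pass with the replicate block (adjusted p = 0.0568). Without the 3 arrays that held adipocyte transcripts neither Mvd (-0.45, adjusted p = 0.0685) nor Msmo1 (-0.50, adjusted p = 0.0579) passed, with changes of about the same size.

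Fatty acid and phospholipid synthesis went down in most of the members that moved. In the fatty acid and triglyceride synthesis list 5 of 22 genes fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.446 with an estimated correlation). Agpat2, an acyltransferase of glycerolipid synthesis, changed by -1.05 ± 0.10 and Mlxipl, which encodes the glucose-responsive factor ChREBP, by -0.70 ± 0.09. The 2 that rose were Cidec, above, and Mogat1 (1.63 ± 0.14), a monoacylglycerol acyltransferase. Without the 3 arrays that held adipocyte transcripts the list did not pass (adjusted p = 0.0552), with a median of -0.20 against -0.19 over all arrays, nor did it without the 8 arrays of the widest removal below (median -0.09, adjusted p = 0.262). In the list of polyunsaturated fatty acid and phospholipid synthesis 6 of 18 genes fell and 1 rose, with the same counts adjusted over the list alone. Its median was -0.002 (camera adjusted p = 0.00727, and adjusted p = 0.0526 with an estimated correlation). The elongase Elovl5 changed by -0.86 ± 0.13, the choline-phosphate enzyme Pcyt1a by -0.58 ± 0.08, choline kinase Chka by -0.56 ± 0.11 and the desaturase Fads2 by -0.39 ± 0.06.

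Among genes of fatty acid oxidation under PPARalpha most did not pass, and more rose than fell. In that list 8 of 29 genes rose and 1 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000406, and adjusted p = 0.519 with an estimated correlation; fry adjusted p = 0.157). Vnn1 rose by 1.47 ± 0.25, Cd36, a fatty acid uptake protein, by 1.41 ± 0.20, Pdk4, which restrains pyruvate oxidation, by 1.29 ± 0.17, and the peroxisomal thiolase Acaa1a by 0.41 ± 0.07.

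Of the carbohydrate and amino acid genes that moved, more fell than rose. Of 13 glycolysis genes 4 fell and 1 rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.24 with an estimated correlation). The call was lost without knockout 3 (adjusted p = 0.0585) and after quantile normalization (adjusted p = 0.0527). Pyruvate kinase Pklr changed by -1.08 ± 0.14, Pdk1, which inhibits pyruvate dehydrogenase, by -0.74 ± 0.13, ketohexokinase Khk by -0.60 ± 0.15 and Gckr by -0.33 ± 0.09. Of 18 genes of gluconeogenesis and glycogen 3 fell and 0 rose, or 3 and 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.223). The 3 were Ppp1r3b (-0.71 ± 0.13), a targeting subunit for glycogen synthesis, Fbp1 (-0.32 ± 0.08) and Ugp2 (-0.31 ± 0.08). Of 21 genes of glutamine, amino acid and urea metabolism 7 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 7.87e-05, and adjusted p = 0.0853 with an estimated correlation). Among them the transaminase Got1 changed by -1.18 ± 0.12, ornithine aminotransferase Oat by -1.02 ± 0.11, N-acetylglutamate synthase Nags by -0.95 ± 0.08 and tryptophan dioxygenase Tdo2 by -0.59 ± 0.07. Of 19 genes of folate and methionine metabolism 8 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.13e-05, and adjusted p = 0.0873 with an estimated correlation). Cth, which makes cysteine, changed by -1.25 ± 0.11, Mthfd1 by -0.85 ± 0.08, Shmt1 by -0.84 ± 0.09 and the glycine methyltransferase Gnmt by -0.81 ± 0.10.

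Of the sex-biased liver genes that moved, the female-biased ones rose and most male-biased ones fell. In the female-biased list 6 of 16 genes rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 2.5e-06, median 0.35). Beside Cyp2b9, the steroid 17-alpha-hydroxylase Cyp17a1 rose by 1.61 ± 0.26, Cyp2b13 by 1.28 ± 0.27 and Slc22a27 by 1.03 ± 0.22. Cyp2b13 (mean 3.00 in controls, 4.28 in knockouts) and Slc22a27 (3.09 and 4.13) were dim. Knockout 3 (3.46) and knockout 7 (2.98) in Cyp2b13 lay within the control range, as did knockout 7 (3.15) and knockout 8 (2.96) in Slc22a27. In the male-biased list 7 of 17 genes fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 2.34e-06, and adjusted p = 0.0985 with an estimated correlation). Hsd3b5 changed by -1.76 ± 0.30 and the elongase Elovl3 by -0.84 ± 0.10, beside Susd4 and Slco1a1 above. None of the 4 sex-linked transcripts measured passed in limma, and 1 had an unadjusted p under 0.05. The Y-linked Kdm5d, Eif2s3y and Uty were at 6.01 or more in every liver, and Xist lay between 2.99 and 3.63.

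Genes of xenobiotic metabolism went both ways. Of 26 measured, 8 rose and 3 fell, or 11 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0561). The call was gained under some alternatives, with adjusted p = 0.00705 without knockout 8 and 0.0198 after quantile normalization. Cyp2a5 rose by 0.56 ± 0.07, while Cyp2c37 changed by -1.25 ± 0.15. Of 17 NRF2 genes 2 rose and 0 fell, with the same counts adjusted over the list alone, namely Nqo1 (0.41 ± 0.09) and Srxn1 (0.39 ± 0.09). The list was not called (camera adjusted p = 0.0957), though it passed without control 6 (adjusted p = 0.0341), with fry (0.0177) and narrowly after quantile normalization (0.05 as rounded).

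Acute phase genes were higher in count, with 9 of 24 up and 1 down, or 10 and 2 adjusted over the list alone. Mt2, a metallothionein, rose by 2.45 ± 0.34, lipocalin Lcn2 by 2.27 ± 0.25 and Orm2 by 1.22 ± 0.17, while Itih3 changed by -1.32 ± 0.12. The list was called higher (camera adjusted p = 0.0124, and adjusted p = 0.54 with an estimated correlation). The call rested on knockout 3, whose list mean was 10.43 against 9.83 or less in the other knockouts, and without it adjusted p was 0.171. It was also lost with array weights (adjusted p = 0.127) and among genes above the 50th percentile of intensity (adjusted p = 0.131).

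Among proliferation genes 9 of 17 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 1.05e-10, median 0.36). Ccnd1, which encodes cyclin D1, rose by 1.82 ± 0.12, Ccna2 by 0.94 ± 0.11 and Mki67 by 0.84 ± 0.11. Cdkn1a, which encodes the cell cycle inhibitor p21, is a member of the list and counted among the 9, and it rose by 1.55 ± 0.22.

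Among liver nuclear receptors and transcription factors more members fell than rose. Of 27 measured, 8 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.5e-06). Beside Nr0b2 and Nr1h4, Cebpa changed by -0.72 ± 0.10, while Pparg rose by 0.82 ± 0.18. Of 19 secreted hepatocyte proteins 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.231 with an estimated correlation), and after quantile normalization adjusted p was 0.0527. Serpina6, the corticosteroid-binding globulin, changed by -1.26 ± 0.11, antithrombin Serpinc1 by -0.28 ± 0.05, Ambp by -0.24 ± 0.05 and plasminogen Plg by -0.21 ± 0.05, which did not pass with the replicate block (adjusted p = 0.0638). Pericentral genes fell in 6 of 20 and rose in 3, with the same counts adjusted over the list alone. They included Rhbg, Oat and Cyp2c37 among the decreases and Cyp2a5 among the increases. The list was called lower (camera adjusted p = 0.0342, and adjusted p = 0.393 with an estimated correlation). That call was also lost after quantile normalization (adjusted p = 0.0692), median centring (0.0563), with array weights (0.0959), among genes above the 50th percentile of intensity (0.0655) and without control 3 (0.0505), control 4 (0.0522), control 5 (0.0817) or knockout 8 (0.131). Periportal genes moved both ways, 4 higher and 3 lower of 16, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.868). Aldh1b1 changed by -1.71 ± 0.15 and Ctsc by -0.89 ± 0.16, and Cyp2f2 rose by 0.28 ± 0.05.

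Few members moved in the lists for the clock, stress and respiration. In the clock list, 1 of 15 genes rose (Wee1, 0.54 ± 0.12) and 1 fell (Arntl, -0.26 ± 0.07), or 1 and 2 adjusted over the list alone (camera adjusted p = 0.181). In the endoplasmic reticulum stress list, 2 of 22 genes fell and 0 rose, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.872). They were Atf4 (-0.32 ± 0.08) and Plk3 (-1.13 ± 0.31), and Plk3 no longer passed with an intensity trend and robust variance (adjusted p = 0.0745) or without control 7 (0.0555). The median of this list was 0.06, its mean -0.05, and camera pointed down where fry pointed up. Of 23 respiratory chain genes 1 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.772): Sdha (0.21 ± 0.05) and Sdhc (-0.24 ± 0.07), of which Sdhc lost its call in 9 of the fits that left out 1 array, with adjusted p up to 0.0795, and with the replicate block (0.058), and Sdha after median centring (0.0545). In the interferon list 3 of 18 genes rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0957), and the list passed without control 3, control 5, control 7, knockout 5 or knockout 8 (adjusted p from 0.0261 to 0.0496). Oasl1 rose by 0.73 ± 0.15, Oasl2 by 0.45 ± 0.10 and Usp18 by 0.69 ± 0.19, which lost its call in 7 of the fits that left out 1 array (adjusted p up to 0.0628), after median centring (0.0592) and with an intensity trend and robust variance (0.0554), and Stat2 changed by -0.35 ± 0.08.

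Among the other cell types of the liver, more markers of stellate cells and cholangiocytes rose than fell. Of 20 stellate cell and fibroblast genes 6 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 7.87e-05, and adjusted p = 0.14 with an estimated correlation). The matrix genes Dcn (0.43 ± 0.07), Tgfbi (0.48 ± 0.10) and Reln (0.43 ± 0.10) rose, while Lrat, which stores retinol in stellate cells, changed by -0.54 ± 0.12. Of 12 cholangiocyte genes 4 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 7e-04, and adjusted p = 0.0873 with an estimated correlation). These were Pkhd1 (0.79 ± 0.09), Cd24a (0.78 ± 0.14), Tspan8 (0.58 ± 0.08) and Epcam (0.31 ± 0.08). Tspan8 was dim, with means of 3.54 in controls and 4.13 in knockouts. Of 18 Kupffer cell and macrophage genes 4 rose and 0 fell, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.219). Lyz2 rose by 0.58 ± 0.12, Cd14 by 0.51 ± 0.13, Ccr2, a dim gene (mean 3.40 in controls, 3.82 in knockouts), by 0.42 ± 0.10 and Gpnmb by 0.32 ± 0.10 (limma adjusted p = 0.0449). Gpnmb lost its call in 11 of the fits that left out 1 array (adjusted p up to 0.1), after quantile normalization (0.0846) and after median centring (0.0964).

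The remaining cell type lists were not called. For lymphocytes 0 of 14 genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.154), and 2 had an unadjusted limma p under 0.05, with Ptprc at 0.23 ± 0.07 (limma adjusted p = 0.058) and Nkg7 at 0.18 ± 0.08. Ptprc passed among genes above the 25th (adjusted p = 0.0455) and the 50th percentile of intensity (0.0336) and without control 2 (0.0222), knockout 6 (0.0374) or knockout 8 (0.0383). Neutrophil genes also gave 0 of 12 both ways (camera adjusted p = 0.682), and 1 had an unadjusted limma p under 0.05, with Cxcr2 at 0.32 ± 0.13 and Mmp9 at -0.18 ± 0.10. Of 16 sinusoidal endothelial genes 0 rose and 1 fell both ways, Ehd3 (-0.38 ± 0.10), and the list had a median of 0.02 and a mean of -0.04 with a camera adjusted p of 0.456. Of 3 red blood cell genes measured, too few for a list test, Alas2 changed by -0.35 ± 0.08. Of 8 adipocyte genes Cidea rose and Car3 changed by -0.38 ± 0.11, the same adjusted over the list alone (camera adjusted p = 0.772). The median of that list was -0.21, its mean 0.18, and camera pointed down where fry pointed up. Car3 lost its call without control 5, control 7, control 8 or knockout 3 (adjusted p from 0.053 to 0.0613). Exocrine pancreas genes gave 0 of 8 both ways (camera adjusted p = 0.872) and 1 at an unadjusted limma p under 0.05, with a median of 0.03, a mean of 0.01 and opposite signs of camera and fry. Cela1 stood at -0.18 ± 0.07 and passed after quantile normalization (adjusted p = 0.0437) and median centring (0.0345), and Cela3b at 0.14 ± 0.11.

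**Figure D2:**
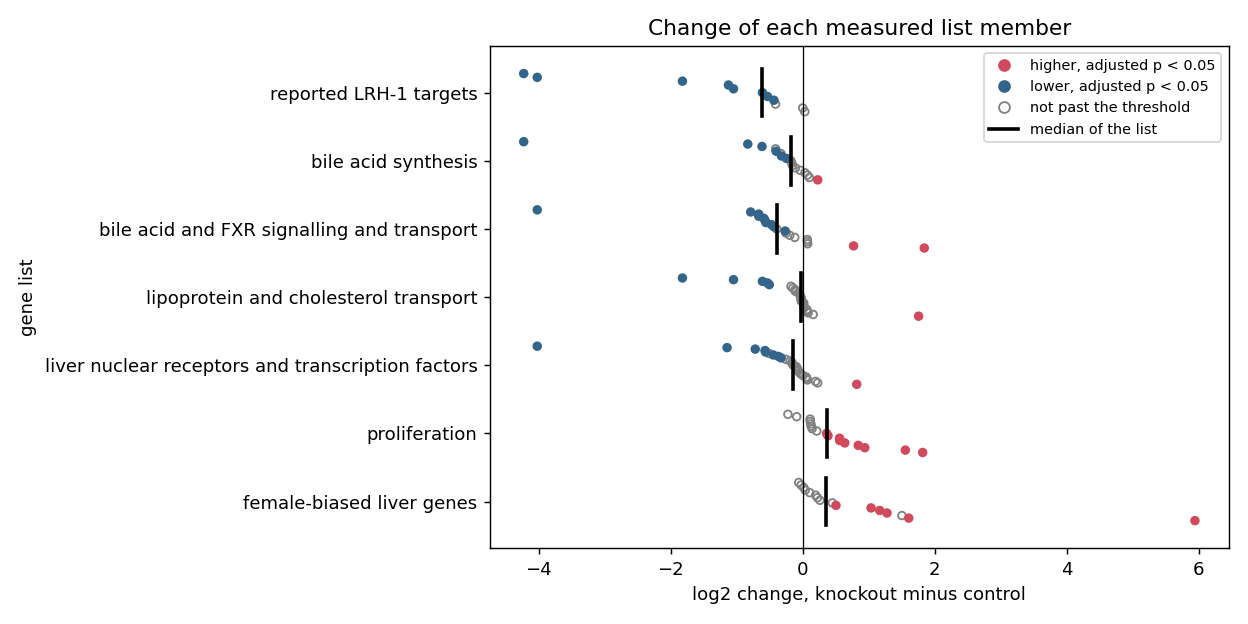
Log2 change, knockout minus control, of every measured member of the 7 lists called with an estimated correlation. Red and blue points are genes higher or lower at a limma adjusted p under 0.05, open points did not pass, and black lines mark list medians, from -0.61 for reported LRH-1 targets to 0.36 for proliferation.

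Over the 34 lists tested, camera called 6 higher and 14 lower. The calls that held with an estimated correlation were 2 higher, female-biased genes (adjusted p = 0.0143) and proliferation (0.00374), and 5 lower. The 5 were reported LRH-1 targets (2.82e-05), bile acid synthesis and FXR signalling and transport (0.00454 each), and lipoprotein transport and nuclear receptors (0.0498 each). These lists overlap. Scarb1, Abcg5, Abcg8 and Apom are members of both the targets and the lipoprotein list. Nr0b2 is a member of the targets, FXR and nuclear receptor lists, and Nr1h4 of the FXR and nuclear receptor lists. The medians of the lipoprotein and nuclear receptor lists were -0.03 and -0.14. Fry called 6 higher and 12 lower, which were not all lists that camera called. It did not call fatty acid oxidation (fry adjusted p = 0.157) or the acute phase (0.206) higher. Nor did it call cholesterol synthesis (fry adjusted p = 0.0547) or fatty acid and triglyceride synthesis (0.211) lower. In their place among the higher lists stood xenobiotic metabolism (fry adjusted p = 0.00967) and NRF2 (0.0177), which camera did not call.

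Single arrays carried transcripts of other tissues. Skeletal muscle genes stood above the other arrays of the genotype by a median of 2.15 log2 units in control 4 and 1.86 in knockout 5. Adipose genes stood above by 1.04 in control 5 and 0.82 in knockout 1, with 0.24 in control 8. The first principal component (27.4% of the variance) separated the genotypes. On the second (21.2%) control 1 (26.6) and knockout 8 (33.3) stood apart from the rest on one side. Knockout 4 (-24.4) was lowest on the other and was kept in the fits without control 1 and knockout 8. Control 1 had the highest median log2 intensity of the 16 arrays (5.442) and knockout 4 the lowest (5.281). Without the 5 arrays with muscle or adipose transcripts 893 genes changed, within the 775 to 1739 found in 40 random draws of as many arrays of each genotype left out, and 865 of them were among the 1673. That fit ended the calls of 28 of the 117 named genes besides Nr5a2, namely Cyp27a1, Cyp46a1, Cyp2b13, Slc22a27, Acaa1a, Atf4, Fbp1, Serpinc1, Ambp, Plg, Nqo1, Srxn1, Arntl, Sdha, Stat2, Cd14, Ccr2, Lrat, Epcam, Ehd3, Alas2, Mvd, Msmo1, Plk3, Sdhc, Usp18, Car3 and Gpnmb, all with an adjusted p of 0.000649 or higher over the 16 arrays. Their changes were a median of 0.93 times those over all arrays (0.75 to 1.13). Without these 5, control 1, knockout 8 and knockout 3, 25 of the named genes lost their calls, 21 of them among the 28 and the other 4 being Cyp17a1 (1.13, adjusted p = 0.124), Ppp1r3b (-0.49, adjusted p = 0.06), Cyp2f2 (0.24, adjusted p = 0.112) and Lyz2 (0.47, adjusted p = 0.0748), and the 25 changes were a median of 0.88 times those over all arrays (0.45 to 1.28).

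**Figure D3:**
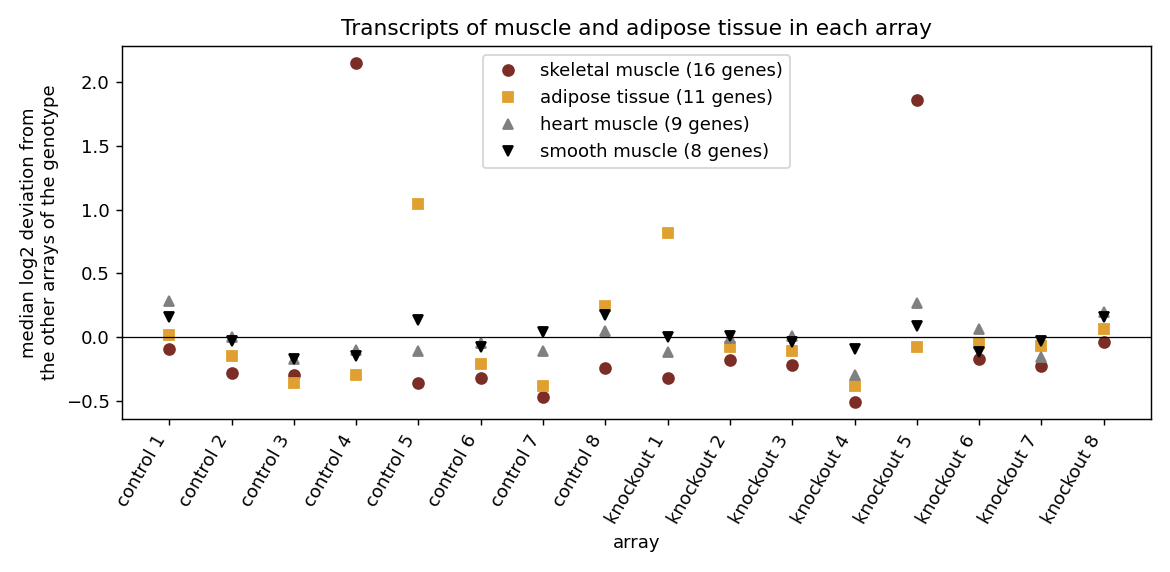
Median log2 deviation of the genes of 4 tissue lists in each array from the mean of the other arrays of its genotype. Skeletal muscle genes (brown circles) stand out in control 4 and knockout 5, at 2.15 and 1.86, and adipose genes (yellow squares) in control 5 and knockout 1, at 1.04 and 0.82.

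A probe set can also read a close relative of its gene, so changes in P450, organic anion transporter and orosomucoid families are uncertain as to the family member. Of the named genes, 18 had a liver far from the rest of its group, 9 of them through knockout 8 and 4 through knockout 3.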

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

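The tests of muscle, adipose tissue, sex, shared P450 sequence, CAR and hepatocyte share were chosen only after the result they bear on had been seen. Each named gene and each list mean was searched within each genotype for a liver whose gap to its nearest neighbour was large against the range of the 8 livers (Dixon's test). This found 27 in 306 groups of 8 values, where chance gives about 1 in 20, or 15.3. Knockout 8 accounted for 12 of them and knockout 3 for 6.

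In knockout 8, Smcp was 5.71 (other knockouts 7.15 to 8.08), Apom 7.12 (6.17 to 6.52), Pdk1 6.13 (6.74 to 7.27), Khk 8.67 (9.57 to 10.09), Fbp1 11.43 (11.92 to 12.12), Tdo2 10.93 (11.23 to 11.46), Ctsc 7.82 (8.49 to 9.05), Usp18 6.44 (7.38 to 7.93) and Ehd3 8.37 (8.84 to 8.99). Its list means were 9.86 for folate and methionine metabolism (9.57 to 9.70), 9.18 for xenobiotic metabolism (9.50 to 9.70) and 8.45 for pericentral genes (8.64 to 8.80). It had the lowest correlation with its group mean of all 16 arrays, 0.9857. In knockout 3, Apof was 10.73 (10.22 to 10.45), Gckr 8.90 (9.32 to 9.59), Mthfd1 8.25 (8.60 to 8.85) and Shmt1 7.90 (8.16 to 8.39), and the list means were 8.79 for cholesterol synthesis (9.25 to 9.48) and 10.43 for the acute phase (9.46 to 9.83).

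Among controls, Cib3 was 5.72 in control 2 (others 4.82 to 5.19), Cidea 6.41 in control 5 (4.06 to 5.16), Fads2 11.23 in control 6 (11.39 to 11.53), Nqo1 4.68 in control 8 (5.02 to 5.31) and Sdha 10.99 in control 3 (10.85 to 10.92). The mean of the bile acid synthesis list was 9.90 in control 3 (9.71 to 9.79), that of the endoplasmic reticulum stress list 8.44 in control 3 (8.78 to 8.93) and that of the NRF2 list 8.07 in control 6 (7.96 to 8.01). The adipocyte list mean was 7.61 in knockout 1 (5.85 to 6.39 in the other knockouts).

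Probe sets outside the gene-level comparison also differed between genotypes in limma at a Benjamini-Hochberg adjusted p under 0.05. They were 106 of the 2376 paired with several genes (69 higher, 37 lower) and 193 of the 11724 not listed in the annotation (116 higher, 77 lower).

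The first pattern is that of the sex-biased genes that moved, the female-biased ones rose and most male-biased ones fell in knockout. Female livers among the knockouts are excluded by the Y-linked transcripts, whose mean lay within 1 log2 unit of the control mean in 8 of 8 knockout arrays. Sequence shared between P450 genes was tested with the 10 female-biased genes outside the Cyp family, of which 3 rose and 0 fell. As a list they were called higher at the preset correlation (camera adjusted p = 0.0181). With an estimated correlation their adjusted p was 0.0811, so a rise of the list beyond its P450 genes is not settled. A general activation of genes responsive to the xenobiotic receptor CAR stays open: of 16 such genes outside both lists 6 rose (Cyp2c55, 2.78, and Cyp2b10, 1.73, the most) and 2 fell (Cyp2c37, -1.25, and Abcc3, -0.67). A shift of sex-biased expression that follows from the loss of LRH-1 may underlie the pattern, as a hypothesis that these data do not separate from CAR activity.

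The second pattern is the presence of transcripts of other tissues in single arrays. Skeletal muscle carried over with the liver piece is a candidate source in control 4 and knockout 5, where 16 muscle genes outside those that drew attention had a median deviation of 2.15 and 1.86 from the other arrays of the genotype (highest median elsewhere -0.04), with Neb at 9.32 and 9.03 against a median of 6.98 in the rest. A general rise of dim probe sets is excluded there, since heart and smooth muscle genes reached at most 0.15 of that deviation. Adipose tissue is a candidate source in control 5 and knockout 1, where 11 adipose genes had a median deviation of 1.04 and 0.82 (highest median in the arrays not in question 0.06), while control 8, at 0.24 (SE 0.08), missed the 0.5 set for a source; the test was first set for these 3 arrays together, where any value under 0.25 counted against adipose tissue and 0.24 did so, and only after that value was seen was control 8 taken apart and its error allowed for, by which it stays open there. Of these genes 4 of the 16 and 2 of the 11 lay above the median gene in the other arrays, and Retn, of the fixed adipocyte list, was 8.51 in control 5, 7.41 in control 8 and 7.95 in knockout 1 against 5.82 or less elsewhere.

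The third pattern is that more stellate cell and cholangiocyte markers rose than fell in knockout. A lower share of hepatocytes would raise the markers of every other cell type alike, and the stellate score minus the endothelial score differed between genotypes by 0.248 (SE 0.078, exact permutation p = 0.00528, adjusted over 4 such comparisons 0.0211) and the cholangiocyte score minus the endothelial score by 0.275 (SE 0.093, exact permutation p = 0.0112, adjusted 0.0224). Against the Kupffer cell score the differences were 0.129 (exact permutation p = 0.213) for stellate cells and 0.156 (exact permutation p = 0.126, adjusted 0.168) for cholangiocytes, so a shared rise with macrophage markers was not excluded. The calls did not need control 1 and knockout 8, high on the second principal component. Without them both lists stayed called at the preset correlation, with camera adjusted p of 0.000639 or lower. That fit kept knockout 4, at the other end of the component (-24.4), so it does not exclude a part of the component as a whole. A change of these cells or of their expression in knockout livers may be considered as a hypothesis, and neither call held with an estimated correlation.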

How the results depend on the processing

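The fits without muscle, adipose or otherwise doubted arrays, and the random removals, were chosen after the data were seen. Across all alternatives no call turned its direction. The 1673 genes changed became 421 with a minimum change of 1.5-fold. Without the 5 arrays with muscle or adipose transcripts they became 893 (586 higher, 307 lower) and without these, control 1, knockout 8 and knockout 3, 1043 (638 higher, 405 lower). Random removal of as many arrays of each genotype gave 775 to 1739 (median 1021.5) and 287 to 1156 (median 674) in 40 draws each. Both counts lay within these ranges, 893 below its median and 1043 above it, so fewer arrays alone can give falls of this size. Camera called 2 lists higher and 5 lower with an estimated correlation. In the other fits the count lay between 1129 and 2094. Leaving out each array in turn gave 1424 to 1821 genes changed (878 to 1154 higher, 527 to 697 lower), 5 to 8 lists higher, 13 to 14 lists lower and a change of Nr5a2 between -0.95 and -0.81. A fit with the replicate number as a block (replicate block) called 1524 genes, 1431 of them among the 1673. The numbers did not pair the livers: the correlation of deviations within equal numbers ran from -0.26 to 0.23, 2 of 8 pairs exceeded 0.1, and 1 of 8 controls correlated best with its own number. Of 117 named genes besides Nr5a2, 83 kept direction and side of the threshold in all refits and 107 in those listed before the data were examined, a count that leaves out the 1.5-fold minimum, which 69 of the 117 met, and all probe sets. Removing arrays that carried adipose transcripts raised the change of Cidec from 2.83 to 3.21 and of Cidea from 2.78 to 3.06. Dim genes limit the comparison, since a signal near background understates a change.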

Other observations

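The tests below of gene families, of other genes and of residual Nr5a2, and the count of splits for lists with an estimated correlation, were chosen only after the results had been seen. Of 20 gene families 5 passed a test for more changed genes than the 8.7% of all genes tested. Of 88 Cyp genes 13 rose and 15 fell (Fisher's exact test against all other genes, adjusted over 20 families, p = 1.36e-08), of 17 Gst genes 5 rose and 3 fell (adjusted exact p = 0.000255), of 48 Abc transporters 7 rose and 7 fell (adjusted exact p = 0.000255), of 368 Slc transporters 30 rose and 23 fell (adjusted exact p = 0.00123) and of 20 Aldh genes 2 rose and 4 fell (adjusted exact p = 0.0229). Genes are not independent replicates in these tests. None of these 5 families moved in a single direction, and the balance depended on the scaling: after each array was centred on its median the counts for Slc were 24 higher and 26 lower, and after quantile normalization those for Aldh were 4 and 4. Other families of metabolic and secreted proteins did not pass: Ugt (2 higher and 0 lower of 11, adjusted exact p = 0.417), Sult (1 and 2 of 16, 0.416), Acot (2 and 0 of 12, 0.417), Apo (0 and 4 of 26, 0.417) and Serpin (3 and 3 of 47, 0.417). Families of ribosomal (2 higher and 2 lower of 84), proteasome (1 and 0 of 44) and NADH dehydrogenase genes (0 and 1 of 43) did not pass. Nor did Cdc (5 higher and 0 lower of 31, adjusted exact p = 0.416), Kif (1 and 0 of 36, 0.459) or Mcm (0 and 1 of 10, 0.629).

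Of the 15 increases and 15 decreases that rank next after the 10 largest each way, 11 were chosen after their values were seen. Tmeff2 rose by 2.60 ± 0.15 (SE), Tinag by 2.58 ± 0.11, Ntrk2, which encodes the neurotrophin receptor TrkB, by 2.25 ± 0.09, the orphan receptor Gprc5b by 2.15 ± 0.14, Mtnr1a, a melatonin receptor, by 2.09 ± 0.12 and Corin, the protease that activates natriuretic peptides, by 1.83 ± 0.12. None of these overlapped between genotypes. Among decreases, Gramd1c changed by -1.72 ± 0.09, Ttc39c by -1.53 ± 0.11, Hes6 by -1.53 ± 0.10, the taurine synthesis enzyme Csad by -1.42 ± 0.22 and the kynurenine aminotransferase Kyat3 by -1.42 ± 0.13. These 11 had limma adjusted p of 0.000159 or lower. Those passed over include Ly6d (2.46 ± 0.29), Cyfip2 (2.39 ± 0.13) and Elapor1 (2.23 ± 0.17) among increases and Cyp2c38 (-1.88 ± 0.39, limma adjusted p = 0.00269) and Slc17a8 (-1.38 ± 0.23, limma adjusted p = 0.000379) among decreases, of which the last 2 overlapped between genotypes.

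The 1673 genes changed were compared with 100 splits of the 16 arrays into 2 groups of 8. The real split gave the most, so 1 of 100 splits gave as many genes, and the highest of the others called 138, which excludes chance as the source. For the 20 lists called at the preset correlation chance is not excluded, and the splits cannot decide it. As many were called in 5 of 100 splits, the real one included, and the others reached up to 22 and called 8 in the median. The others with 20 or more held 2 or 6 controls in the first group of 8, so they kept part of the genotype contrast. Among splits with 4 controls in that group the highest count was 17. With an estimated correlation the real split called 7 lists and was the only 1 of 100 to do so, with 1 list as the highest of the others. The other splits there also kept the genotype contrast to differing degrees. Taken list by list, the real split had the smallest camera p of the 100 for reported LRH-1 targets, bile acid synthesis, FXR signalling and transport, lipoprotein transport, folate and methionine metabolism, nuclear receptors, female-biased genes and proliferation. For fatty acid oxidation 41 of 100 splits had as small a p, for the acute phase 42, for fatty acid and triglyceride synthesis 29, for pericentral genes 17, for cholesterol synthesis 15, for glycolysis 14, for stellate cells 8, for secreted hepatocyte proteins 5, for cholangiocytes 4, for polyunsaturated fatty acid and phospholipid synthesis and for male-biased genes 3 each, and for amino acid metabolism 2.

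Residual Nr5a2 ranged from 7.25 to 8.25 among knockout livers. The hypothesis that incomplete deletion left target expression was tested across the 8 knockout livers, where the mean of the reported targets gave Spearman's rho = 0.50 (exact permutation p = 0.216) and Pearson's r = 0.37 (exact permutation p = 0.371, with an adjusted p of 0.371 for each of the 2 relations) with Nr5a2, and r = 0.11 without the 2 livers farthest from the median. The samples are too few to decide it.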
